A study of Mus musculus with 45 samples.

How the data were processed

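Gene expression was measured in 45 mouse mammary tumours, each on its own single-colour Affymetrix array. Pieces of mammary tissue lacking the tumour suppressor gene Trp53 were transplanted into the inguinal fat pads of wild-type BALB/c female mice aged 10 weeks, whose own mammary epithelium had been removed at 3 weeks of age. The hosts, not the transplants, had been exposed to silicon ions or to a sham procedure 3 days earlier. Transplants were followed for up to 600 days and tumours were taken at a size of 1 cm3, per the labels' protocols. Groups were read from the sample titles. There were 18 tumours from sham hosts, 9 from hosts given 10 cGy, 10 at 30 cGy and 8 at 80 cGy, so that 27 tumours came from Si-irradiated hosts. Silicon ions are heavy charged particles that deposit energy densely along their track.

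The deposited values are log2 expression per probe set, and per the submitters' processing notes they came from RMA (background correction, quantile normalization and probe summary) with the oligo package. Versions of these tools are not given in the sources used here. The values ran from 1.34 to 14.06, and the array medians lay between 5.48 and 5.80. Of 35556 probe sets, 21218 had 1 gene symbol in the platform annotation, 1881 had several and 12457 had none in the table used here. Gene identifiers of 21185 of the single-symbol probe sets were found in the RefSeq gene table, and no symbol needed an update. These probe sets covered 18820 genes, of which 1386 had several probe sets and were represented by the one with the highest mean. A gene was kept where its value lay above the median of the table, 5.67, in at least 8 tumours, the size of the smallest group. This left 12123 genes. Trp53 was not analysed here, since no probe set carried its symbol alone.

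Differences were tested with limma 3.58.1 in R 4.3.3. The means of the 4 groups were fitted together (lmFit and eBayes), so that they shared 1 estimate of the spread per gene, and no covariates were used. The contrasts were the unweighted mean of the 3 dose groups minus sham, each dose minus sham, an F test over the 4 groups, a slope on dose in cGy and an F test among the 3 doses. All tests were two-sided, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors given with limma differences are standard errors. Because the number of arrays limits precision, a smaller difference may be missed where it would show with more tumours. In 10 simulated data sets built on the 12123 genes, the test of Si hosts against sham recovered 52.2% of genes shifted by 0.5 log2, 85.8% at 1, 98.8% at 2 and 99.8% at 3. The corresponding shares were 31.8%, 73%, 95.4% and 99.2% for 10 cGy, 33%, 74.2%, 94.6% and 99% for 30 cGy, and 27.4%, 72.2%, 94.8% and 99% for 80 cGy. Genes of all 4 sizes were shifted together in each set, 500 per size over the 10 sets. Many strong shifts ease the adjusted threshold for the rest. These shares therefore do not hold where few genes change, and a change of 1 log2 or more in few genes can be missed. Without any shift, 1 of 10 simulated sets gave calls for 80 cGy (61 genes), 1 for the dose slope (165) and 1 for the test among doses (3), and none did for the other 4 tests.

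The lists of genes, the tests, the filter, the rule for naming genes and most alternatives were fixed before the data were examined. The 37 lists covered epithelial, stromal and immune cell types and signalling or metabolic pathways. The epithelial and tumour lists were luminal epithelium, hormone receptor genes and oestrogen targets, basal and myoepithelial epithelium, squamous and cornified epithelium, epithelial junctions, mesenchymal and claudin-low genes, milk and alveolar differentiation, and mammary stem and progenitor genes. The pathway lists were cell cycle, DNA damage response and repair, p53 targets, TGF-beta targets, Notch, Wnt, Hedgehog, hypoxia and glycolysis, oxidative phosphorylation, inflammatory cytokines, type I interferon, interferon-gamma with MHC class I, the unfolded protein response, ribosomal proteins and immediate early genes. The lists for other cells were T cells, B and plasma cells, NK and cytotoxic cells, macrophages and monocytes, dendritic cells with MHC class II, neutrophils, mast cells with basophils and eosinophils, fibroblasts with extracellular matrix, endothelium, adipocytes, skeletal muscle, nerve and Schwann cells, erythroid cells, and lymph node stroma. A tumour's score on a list was the mean over its measured genes of the log2 value minus that gene's mean over the 45 tumours. Score differences were tested by permuting tumours (100000 resamples, Benjamini-Hochberg over the 37 lists). For 10 and 80 cGy all 4686825 and 1562275 arrangements were also enumerated. In simulated data for Si hosts against sham, 48 of 60 lists shifted by 1 log2 were called and 0 of 680 others were. Alternatives with limma's camera and fry were run, and genes were also adjusted within each list. The adjustment within a list did not correct for the number of lists or comparisons, so some passing genes arise by chance.

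Genes were named by rule. For each contrast with sham, up to 12 genes per direction past the threshold were to be named, and where fewer passed, the genes of smallest unadjusted p filled each direction up to 10. Up to 4 genes per list, the 6 genes of smallest p for the F tests and the slope, and Trp53, Esr1, Pgr, Erbb2, Krt18, Krt8, Krt5, Krt14, Krt6a, Cdh1, Vim, Mki67, Tgfb1, Notch1, Kit and Cdkn2a were added. Predicted genes, microRNA genes and snoRNA genes counted in totals but were not named by this rule. Tumour-to-tumour spread was the ratio, Si over sham, of root mean squared distances to the group mean, with a permutation test. Similarity of the dose effects was compared with 1000 simulated sets of unchanged groups against the same sham tumours.

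The labels do not say whether each tumour came from its own host. The 45 sample codes have 37 different stems, and 8 stems occur with both an L and an R, which the labels do not explain. Some tumours may therefore share a host, and p-values measure the spread between these tumours. The codes of 10 sham tumours begin with 5 and those of 8 with 6, also without explanation. Alternatives fixed in advance used no filter or a stricter one (above the median in 23 tumours), the mean of a gene's probe sets, a further normalization, array weights, a trended and robust prior, the code stem as a random block or averaged, the code letter, either sham code alone, the replicate number as a block, only the groups compared, standardized genes, ranks of dose, and each tumour left out in turn. Alternatives added after seeing the data used array differences seen in the unnamed probe sets, an epithelial score as covariate, and the data without tumours rich in muscle or fat or without the most similar pair. Calculations on lists used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.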

Results

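Expression of 12123 genes was compared among 45 Trp53-null mammary tumours. Of these, 18 arose in sham-irradiated hosts, and the others in hosts exposed to 10 cGy (n = 9 tumours), 30 cGy (n = 10) or 80 cGy (n = 8) of silicon ions. Only the hosts were irradiated, so the design asks whether an irradiated host environment goes with a different tumour. Values are log2 expression as deposited after RMA, and array medians lay between 5.48 and 5.80.

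The tumours differed widely from one another within every group. Krt18, a keratin of luminal cells, ranged from 6.38 to 12.90 over the 45 tumours, and Krt5, a keratin of basal cells, from 4.93 to 13.32. Krt14, another basal keratin, ranged from 5.25 to 12.88, Krt6a from 3.31 to 11.68 and Cdh1, which encodes E-cadherin, from 5.56 to 11.62. Vim, which encodes the mesenchymal filament protein vimentin, had a narrower range of 11.90 to 13.58. Pgr, the progesterone receptor gene, ranged from 3.46 to 9.17, Esr1, the oestrogen receptor gene, from 5.12 to 8.65, and Erbb2 from 7.14 to 9.61. The score of the squamous and cornified epithelium list spanned -1.52 to 5.82, that of epithelial junctions -2.98 to 1.42 and that of milk and alveolar differentiation -2.81 to 3.51. The first 3 principal components held 24.7%, 8.62% and 7.94% of the variance. No component differed between sham and any Si comparison by permutation test (lowest adjusted p = 0.464 over 12 tests). Correlations between pairs of tumours over the genes kept had a median of 0.857, and the most alike pair, 10 cGy replicate 1 and sham replicate 16, reached 0.978.

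**Figure D1:**
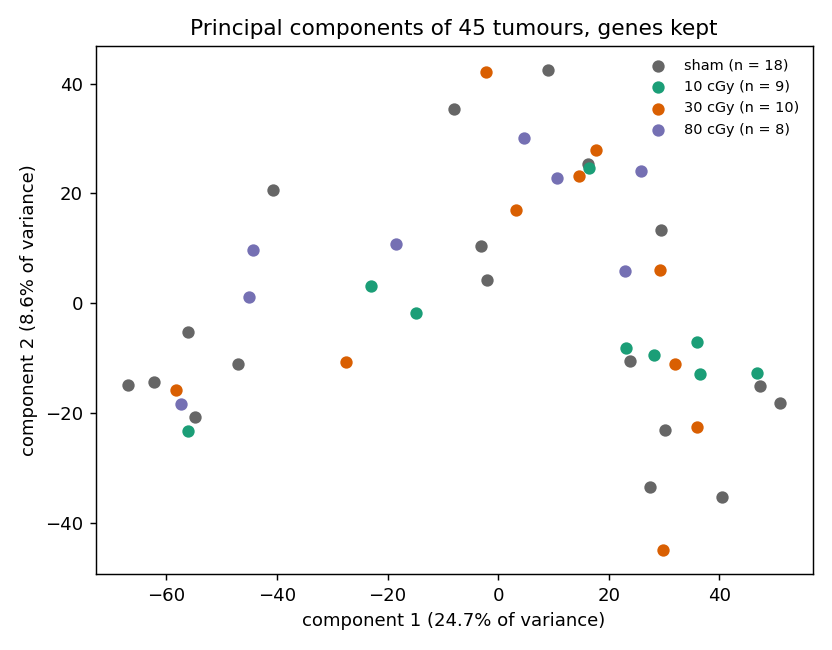
Each point is a tumour placed on the first 2 principal components of the genes kept, which held 24.7% and 8.62% of the variance; axes are component scores and colours are host groups. Tumours of every host group lay on both sides of 0 on component 1.

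**Figure D2:**
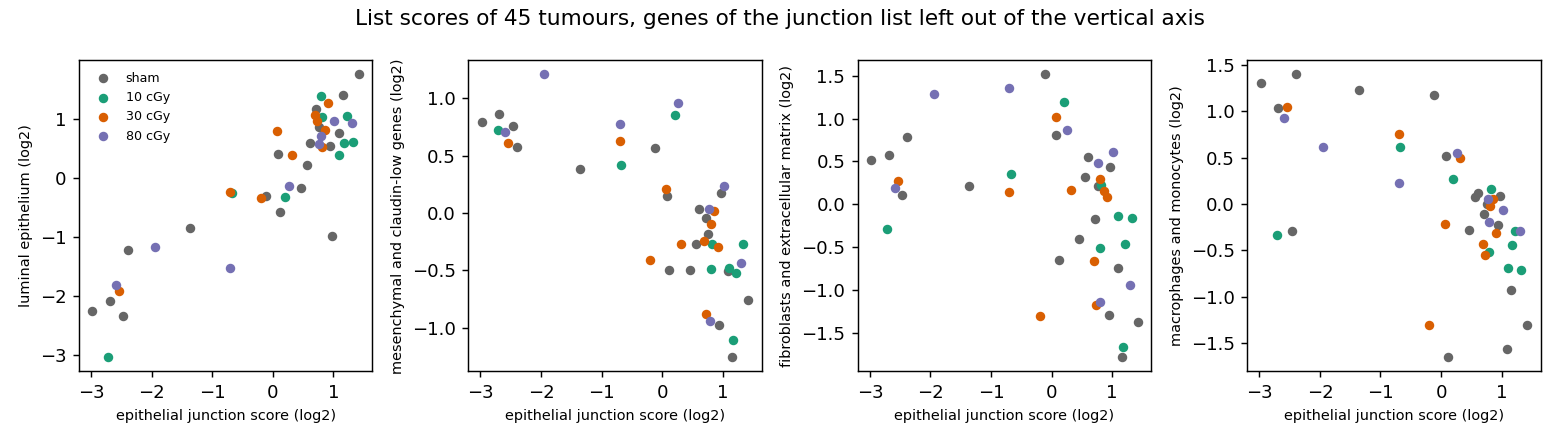
Each point is a tumour; the horizontal axis is its score on the epithelial junction list and the vertical axis its score on the luminal, mesenchymal, fibroblast or macrophage list (mean log2 relative to the gene mean), without genes that are also on the junction list. Scores below the gap between -1.36 and -0.70 belonged to 5 sham tumours and 4 tumours of Si hosts.

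Tumours of Si-irradiated hosts as a whole were first set against tumours of sham hosts. Lpcat4 (probe set 10474526), a lysophospholipid acyltransferase gene of phospholipid remodelling, had a log2 difference of 0.84 ± 0.18 and lay above the sham mean in 25 of 27 tumours. Galnt6 (probe set 10432661), which encodes an enzyme that starts mucin-type O-glycosylation, had a difference of -0.98 ± 0.25 and lay below the sham mean in 27 of 27 tumours. That mean, 6.53 ± 1.16 (SD, n = 18), included 3 sham tumours at 8.34 to 9.01, above every other tumour. None of these differences passed correction for the 12123 genes tested.

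Limma called 0 genes at an adjusted p under 0.05, the lowest adjusted p being 0.251 for Lpcat4. At an unadjusted p under 0.05 there were 706 genes, 425 higher and 281 lower in Si hosts. The other genes with the smallest p on the higher side were Supt20 (0.30 ± 0.08), Zfp458 (0.26 ± 0.07), Ppig, a cyclophilin gene (0.33 ± 0.09), Ndrg3 (0.36 ± 0.10), Wac (0.27 ± 0.07), Rbbp9 (0.42 ± 0.12), Alg8 of N-glycan assembly (0.40 ± 0.12), Slf1 (0.37 ± 0.11) and the Polycomb gene Phc3 (0.32 ± 0.10). On the lower side they were Dip2b (-0.37 ± 0.10), the clathrin light chain gene Clta (-0.29 ± 0.08), the prefoldin gene Pfdn5 (-0.35 ± 0.10), Plekhf2 (-0.26 ± 0.07), Nrip2 (-0.56 ± 0.16), Zbtb48 (-0.26 ± 0.07), the ribonuclease inhibitor gene Rnh1 (-0.29 ± 0.08), Mrpl54 of the mitochondrial ribosome (-0.35 ± 0.10) and Dennd4c (-0.24 ± 0.07). Each of these 18 genes lay on the same side of the sham mean in 22 to 26 of the 27 tumours. These counts, like those of Lpcat4 and Galnt6, come from the tumours in which the genes were chosen by p. They add no separate support. For Lpcat4, Zfp458, Nrip2, Zbtb48, Mrpl54 and Dennd4c, 1 tumour of a dose group lay far from the rest of that group. Without 10 cGy replicate 5, Lpcat4 passed in limma (adjusted p = 0.0303). A component of probe sets without a gene symbol was cut to divide the arrays into 2 sets, which were uneven between groups. Set A held 9 of 18 sham tumours, 3 of 9 at 10 cGy, 5 of 10 at 30 cGy and 1 of 8 at 80 cGy.

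**Figure D3:**
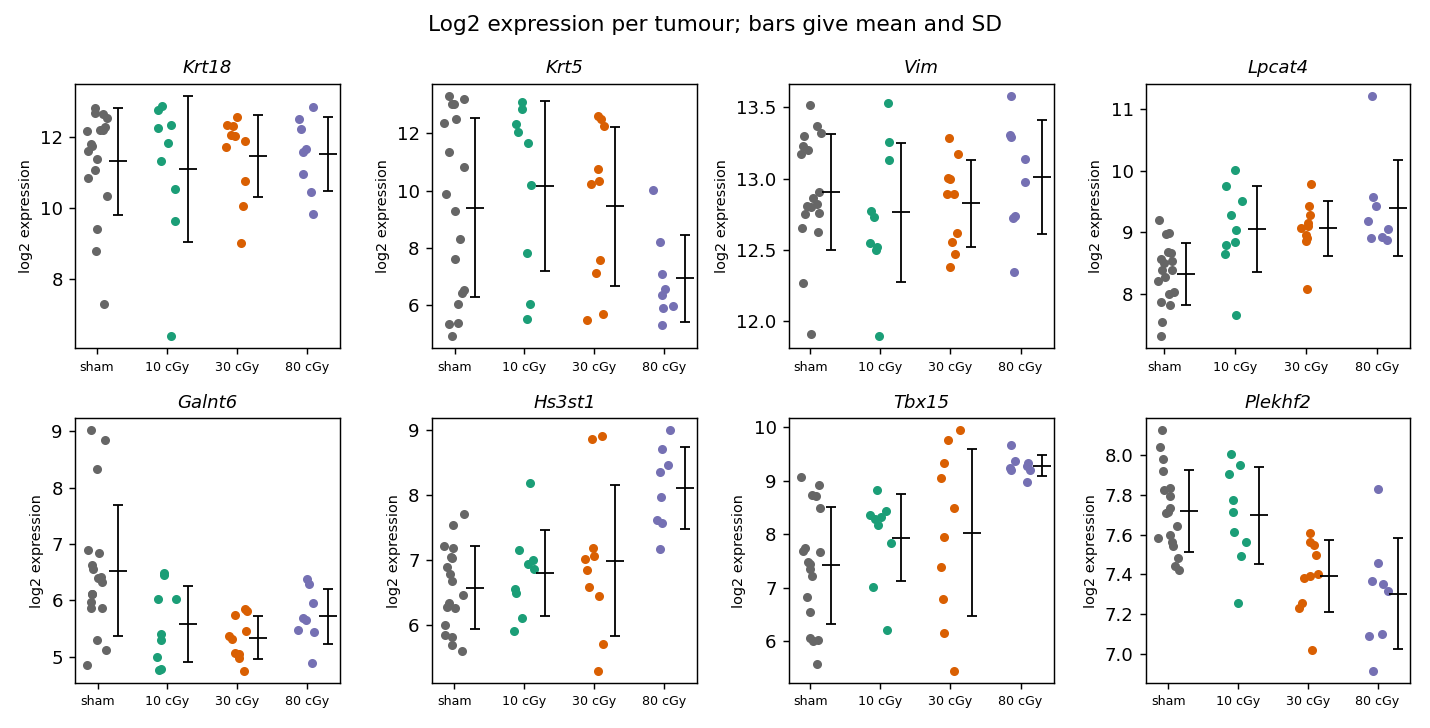
Log2 expression of 8 genes in each tumour by host group, with the mean and SD beside the points. Krt18 and Krt5 spread widely in sham and Si groups, and the 8 tumours at 80 cGy lay between 8.97 and 9.68 for Tbx15 and between 7.18 and 9.00 for Hs3st1.

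Among epithelial lists, luminal epithelium had a score difference of 0.34 ± 0.40 between Si and sham tumours, with 17 of 18 measured genes on the higher side, among them Cd24a (0.56 ± 0.33) and Muc1 (0.73 ± 0.49). Milk and alveolar differentiation differed by 0.55 ± 0.49, with the casein genes Csn1s2a (1.96 ± 0.82) and Csn2 (1.56 ± 0.69) having the smallest p. Epithelial junctions differed by 0.29 ± 0.42 and hormone receptor genes with oestrogen targets by 0.11 ± 0.14, where Ccnd1 had a difference of 0.28 ± 0.13. Basal and myoepithelial epithelium differed by -0.18 ± 0.36 (0.09 ± 0.49 at 10 cGy), and squamous and cornified epithelium by -0.53 ± 0.55, with 9 of 9 genes on the lower side, such as Sbsn (-0.80 ± 0.42), although at 10 cGy the list stood at 0.18 ± 0.91. The mesenchymal and claudin-low list differed by 0.06 ± 0.19 (-0.09 ± 0.26 at 10 cGy and -0.03 ± 0.21 at 30 cGy) and the mammary stem and progenitor list by 0.08 ± 0.13. Among single markers, none of which passed, Esr1 stood at -0.32 ± 0.26, Pgr at 0.16 ± 0.41, Erbb2 at 0.14 ± 0.20, Krt18 at 0.04 ± 0.45, Krt8 at 0.26 ± 0.41, Krt5 at -0.55 ± 0.83, Krt14 at -0.13 ± 0.60, Krt6a at -0.43 ± 0.70, Cdh1 at 0.35 ± 0.52, Vim at -0.04 ± 0.12, Kit at 0.30 ± 0.40 and Cdkn2a at -0.02 ± 0.22.

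Among pathway lists, the cell cycle score differed by 0.03 ± 0.11, and the proliferation marker Mki67 by 0.17 ± 0.13. DNA damage response and repair differed by 0.005 ± 0.089 and p53 targets by -0.012 ± 0.074; in both lists the median gene had the opposite sign to the score (-0.009 and 0.0062). TGF-beta targets differed by 0.18 ± 0.13, with 14 of 17 genes on the higher side, including Pmepa1 (0.43 ± 0.17) and Ltbp2 (0.54 ± 0.22), while Tgfb1 itself stood at 0.11 ± 0.18. Hedgehog differed by 0.19 ± 0.09 (permutation p = 0.0507), with Sufu (0.26 ± 0.12) and Hhip (0.84 ± 0.40), both negative regulators of the pathway, among its genes. Hypoxia and glycolysis differed by -0.17 ± 0.14, with 15 of 17 genes on the lower side, including the hexokinase gene Hk2 (-0.49 ± 0.21). Oxidative phosphorylation differed by -0.04 ± 0.05 (0.04 ± 0.10 at 30 cGy). Of its 20 genes, 2 passed in limma when adjusted over the list alone, Sdhb (-0.37 ± 0.12) and Ndufa1 (-0.32 ± 0.11). That adjustment did not correct for the number of lists, and 0 passed over all genes. Notch differed by -9.0e-05 ± 0.13 (Notch1 0.04 ± 0.18), Wnt by 0.06 ± 0.16, the unfolded protein response by -0.02 ± 0.06, ribosomal proteins by -0.03 ± 0.04 and immediate early genes by -0.13 ± 0.11. Inflammatory cytokines differed by -0.19 ± 0.25 (0.03 ± 0.27 at 80 cGy), type I interferon by -0.11 ± 0.20 and interferon-gamma with MHC class I by 0.10 ± 0.13.

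Among lists of other cell types, mast cells with basophils and eosinophils had the difference with the smallest p after Hedgehog, -0.52 ± 0.30 (permutation p = 0.0553). Its 7 measured genes were all on the lower side, among them the mast cell protease genes Tpsb2 (-0.61 ± 0.27) and Cpa3 (-0.96 ± 0.48), although at 80 cGy the list stood at 0.03 ± 0.33. Neutrophils differed by -0.29 ± 0.37 (0.37 ± 0.45 at 80 cGy), macrophages and monocytes by -0.05 ± 0.25 (0.19 ± 0.27 at 80 cGy), where the scavenger receptor gene Cd163 stood at -0.90 ± 0.35, and dendritic cells with MHC class II by 0.03 ± 0.14. T cells differed by 0.11 ± 0.16, B and plasma cells by 0.15 ± 0.12, NK and cytotoxic cells by -0.004 ± 0.206 and lymph node stroma by 0.22 ± 0.21. Fibroblasts with extracellular matrix differed by 0.03 ± 0.26 (-0.14 ± 0.33 at 10 cGy and -0.08 ± 0.31 at 30 cGy), endothelium by -0.05 ± 0.25 (0.21 ± 0.25 at 80 cGy), adipocytes by -0.15 ± 0.41 (0.18 ± 0.59 at 30 cGy), skeletal muscle by -0.28 ± 0.64, nerve and Schwann cells by -0.01 ± 0.23 and erythroid cells, with 2 measured genes, by -0.08 ± 0.30. Muscle or fat scores above 2 were seen in 4 sham tumours, 1 at 30 cGy and 2 at 80 cGy. Of the 37 lists, 17 were higher and 20 lower in Si hosts, and in 23 of them at least 1 dose lay on the other side. The permutation test called 0 after adjustment (lowest adjusted p = 0.993) and 0 at an unadjusted p under 0.05. Camera with its preset correlation called 4 lists, namely mast cells with basophils and eosinophils, hypoxia, squamous epithelium (lower) and TGF-beta targets (higher). With an estimated correlation camera called 0 of them, each at an adjusted p = 0.931, and fry called 0.

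**Figure D4:**
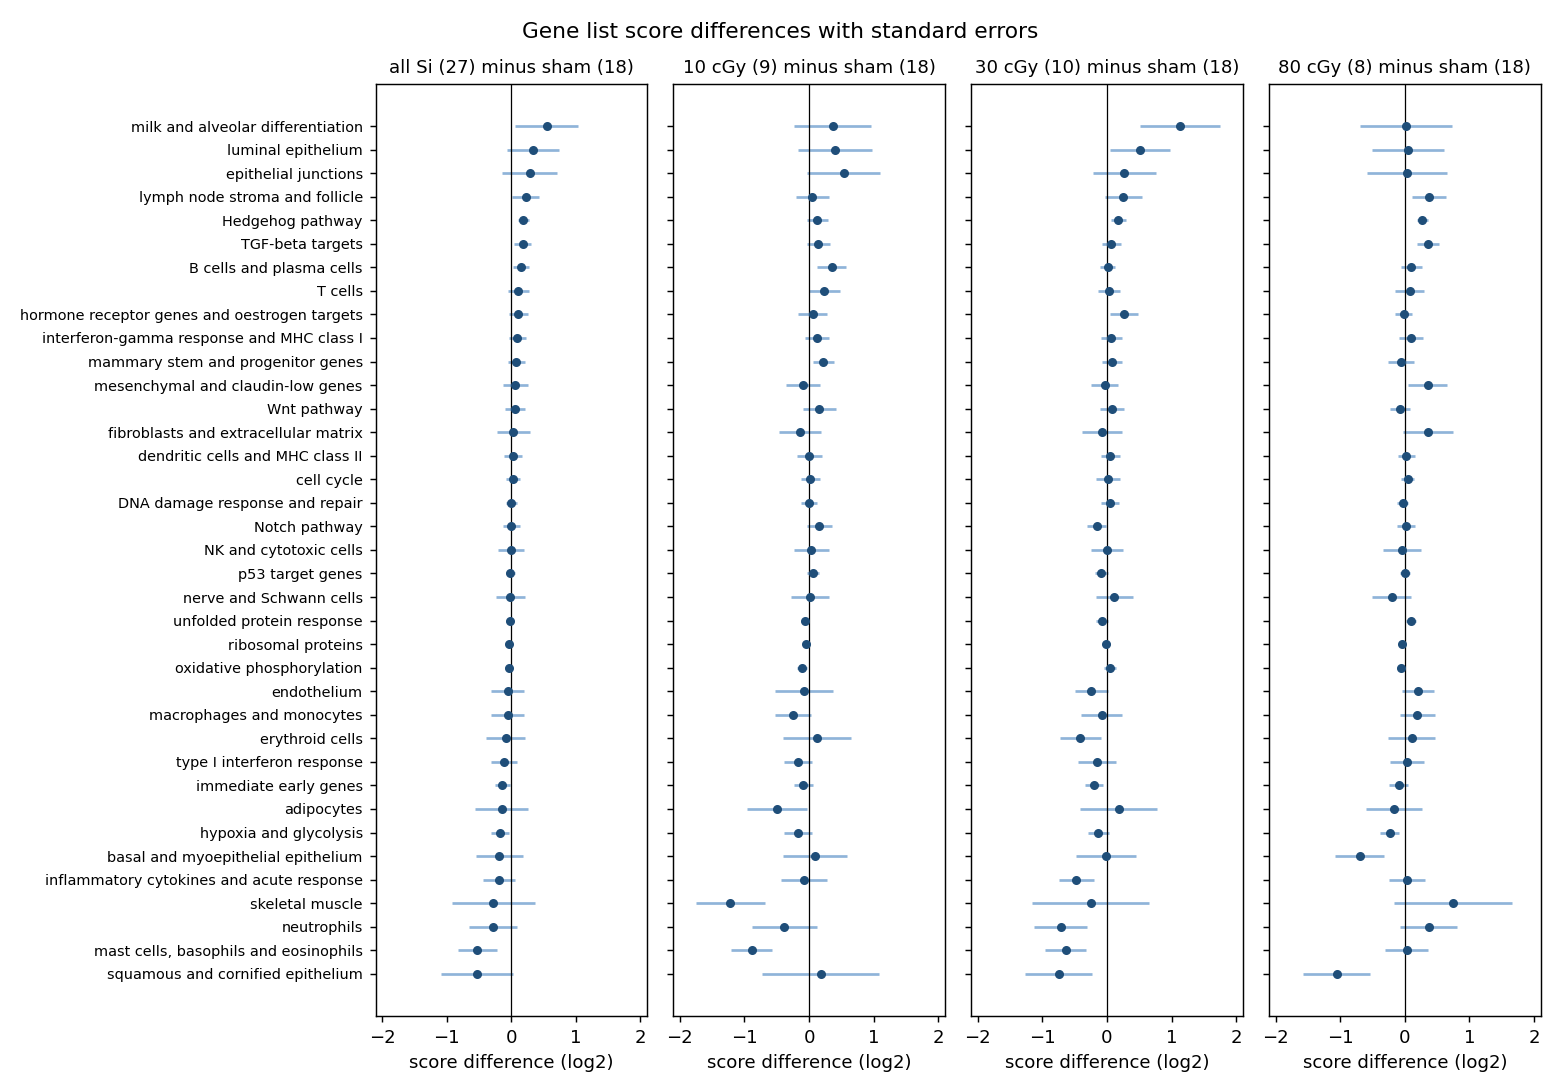
Difference in list score (log2) from the 18 sham tumours for all 27 Si tumours and for each dose, with standard errors, for the 37 gene lists. The differences ranged from -0.53 to 0.55 for all Si tumours, and none passed adjustment in any panel.

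At 10 cGy, Chad, which encodes the cartilage matrix protein chondroadherin, was 1.72 ± 0.49 above sham, with means of 7.15 ± 1.81 (SD, n = 9) and 5.43 ± 0.91 (SD, n = 18). Nrip2 was at -0.77 ± 0.21 and Slc25a4, the gene of a mitochondrial ADP/ATP carrier, at -0.76 ± 0.22. Mast cell genes had the list difference of smallest p, -0.89 ± 0.32, with 7 of 7 genes on the lower side. They included Cpa3 (-1.62 ± 0.64), Mcpt4 (-1.33 ± 0.56), Tpsab1 (-1.11 ± 0.49) and Tpsb2 (-0.95 ± 0.36). The sham mean included replicates 7, 9 and 16, which scored above every tumour of a Si host. Neither the genes nor the list passed adjustment.

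Limma called 0 genes at 10 cGy (lowest adjusted p = 0.991), with 443 at an unadjusted p under 0.05, 244 of them higher. Further genes with the smallest p were, on the higher side, the transcript cleavage factor gene Pcf11 (0.33 ± 0.10), Phc3 (0.44 ± 0.13), Vps54 (0.36 ± 0.11), Cebpg (0.33 ± 0.10), Atad2b (0.38 ± 0.12), Vkorc1l1 (0.43 ± 0.14), Dnajc21 (0.56 ± 0.18), Zfp51 (0.44 ± 0.14) and the mRNA export gene Nxf1 (0.25 ± 0.08), for which replicate 3 lay far from the rest of the group. On the lower side they were the lysosomal gene Aga (-0.59 ± 0.17), the glutaryl-CoA dehydrogenase gene Gcdh (-0.51 ± 0.16), Clta (-0.34 ± 0.10), Myo9b (-0.52 ± 0.16), the coatomer gene Cope (-0.56 ± 0.18), Mrpl2 (-0.33 ± 0.11), Pik3r2 (-0.63 ± 0.21) and the succinate dehydrogenase gene Sdhb (-0.49 ± 0.16). Epithelial junctions differed by 0.54 ± 0.56 with 20 of 20 genes on the higher side, although 10 cGy replicate 1 held the lowest score among the Si tumours. Kit, a receptor gene of luminal progenitors, stood at 1.08 ± 0.53, oxidative phosphorylation at -0.11 ± 0.07, B and plasma cells at 0.35 ± 0.22 with 9 of 9 genes on the higher side, and skeletal muscle at -1.22 ± 0.53 with 14 of 14 on the lower side. None of the 9 tumours at 10 cGy had a muscle or fat score above 2. The permutation test called 0 of 37 lists (lowest adjusted p = 0.873), and mast cells alone had an unadjusted p under 0.05 (permutation p = 0.0369, exact enumeration 0.0371). Genes adjusted over the list alone gave 0 calls in limma. Camera with its preset correlation called 11 lists: epithelial junctions, TGF-beta targets and B cells higher, and hypoxia, oxidative phosphorylation, type I interferon, macrophages, neutrophils, mast cells, adipocytes and skeletal muscle lower. With an estimated correlation camera called 0 (adjusted p = 0.221 for mast cells, 0.719 for B cells and 0.912 for the others), and fry called 0.

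At 30 cGy, Ido1, the gene of an enzyme that breaks down tryptophan and is induced by interferon-gamma, had a mean of 6.17 ± 1.72 (SD, n = 10) against 4.45 ± 0.94 in sham tumours (SD, n = 18), a difference of 1.72 ± 0.47. The interferon-gamma list, which holds Ido1, differed by 0.07 ± 0.17, with 7 of its genes on the higher and 11 on the lower side. Tph1, the gene of tryptophan hydroxylase, stood at 1.44 ± 0.41. Among genes of milk proteins, Csn1s2a was 3.19 ± 1.07, Csn2 2.22 ± 0.90, Csn3 1.87 ± 0.88 and Csn1s1 1.98 ± 1.09 above sham, and 14 of 15 measured genes of the list were on the higher side. Neutrophil genes S100a8 (-1.32 ± 0.57) and S100a9 (-1.25 ± 0.57) were on the lower side with all 13 genes of their list.

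Limma called 0 genes at 30 cGy (lowest adjusted p = 0.536), with 540 at an unadjusted p under 0.05, of which 246 were higher. The lowest adjusted p was that of a snoRNA gene. Below sham, the genes with the smallest p were Tbc1d10a (-0.44 ± 0.11), the ubiquitin ligase gene Rnf41 (-0.36 ± 0.09), the TGF-beta inducible gene Klf10 (-0.56 ± 0.15), the Argonaute gene Ago2 (-0.35 ± 0.09), Cactin (-0.33 ± 0.09), Mrpl54 (-0.48 ± 0.13), Galnt6 (-1.19 ± 0.33), Plekhf2 (-0.33 ± 0.09), Trmt44 (-0.34 ± 0.10) and the autophagy gene Atg16l1 (-0.35 ± 0.11). Above sham were Cwf19l2 (0.72 ± 0.19), the tRNA modification gene Alkbh8 (0.83 ± 0.24), Rfx7 (0.55 ± 0.16), the kainate receptor gene Grik5 (0.64 ± 0.19), Prkar2a (0.41 ± 0.13), Lpcat4 (0.74 ± 0.23), Map7d2 (1.16 ± 0.36) and the netrin receptor gene Unc5c (0.88 ± 0.28). The list scores differed by 1.13 ± 0.62 for milk and alveolar differentiation, -0.72 ± 0.41 for neutrophils, -0.64 ± 0.32 for mast cells, -0.75 ± 0.52 for squamous epithelium, -0.48 ± 0.27 for inflammatory cytokines (Cxcl1 -0.90 ± 0.42, Tnf -0.63 ± 0.29) and 0.51 ± 0.47 for luminal epithelium. The permutation test called 0 of 37 lists (lowest adjusted p = 0.971) and 0 at an unadjusted p under 0.05. Adjusted over the list alone, without correction for the number of lists, Ido1 passed in limma in the interferon-gamma list, and 0 genes passed over all genes. Camera with its preset correlation called 7 lists, luminal epithelium and milk differentiation higher, and squamous epithelium, inflammatory cytokines, neutrophils, mast cells and immediate early genes lower. With an estimated correlation camera called 0 (adjusted p = 0.964 for luminal and squamous epithelium and 0.788 for the others), and fry called 0.

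At 80 cGy, Hs3st1 (probe set 10529732), the gene of a heparan sulfate sulfotransferase, had a mean of 8.11 ± 0.63 (SD, n = 8) against 6.58 ± 0.64 in sham tumours (SD, n = 18), a difference of 1.53 ± 0.33. Tbx15 (probe set 10494672), a T-box transcription factor gene of mesenchymal development, stood at 9.29 ± 0.20 against 7.42 ± 1.09, a difference of 1.86 ± 0.45. Lpcat4 was 1.07 ± 0.25 above sham, with 80 cGy replicate 7 alone at 11.22, and Plekhf2 (probe set 10511498) was at -0.42 ± 0.10. Basal and cornified keratinocyte genes were on the lower side, with Krt5 at -2.47 ± 1.15, Trp63 at -1.29 ± 0.75 and Sprr1a at -2.09 ± 0.87, and the transcription factor genes Snai1 (1.15 ± 0.47), Twist2 (1.14 ± 0.53) and Twist1 (0.60 ± 0.29) were on the higher side. None of these passed over all genes.

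Limma called 0 genes at 80 cGy (lowest adjusted p = 0.342), with 845 at an unadjusted p under 0.05, 579 of them higher. The others with the smallest p above sham were Itprip (0.47 ± 0.12), Zc3h10 (0.39 ± 0.10), Zfp469 (1.07 ± 0.29), Ap3s1 (0.64 ± 0.17), the autophagy gene Atg12 (0.61 ± 0.16), Adat1 (0.44 ± 0.12) and Ndrg3 (0.51 ± 0.14), and below sham Cyp2j9 (-0.93 ± 0.24), Dip2b (-0.50 ± 0.13), Dennd4c (-0.35 ± 0.10), Krtap5-1 (-0.61 ± 0.18), the histone deacetylase gene Hdac8 (-0.39 ± 0.12), Txnip (-0.64 ± 0.20), Meltf (-0.9995 ± 0.31), Nrip2 (-0.71 ± 0.22) and Dennd2c (-0.76 ± 0.24). For Zc3h10 and Atg12, 1 of the 8 tumours lay far above the rest. With array weights, which count tumours far from their group less, limma called 30 genes, 25 of them higher, among them Hs3st1 (adjusted p = 0.0146), Tbx15 (0.022) and Itprip (0.00949). Fitted with the sham tumours as 2 groups only, Hs3st1 passed alone (adjusted p = 0.0421).

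Hedgehog genes differed by 0.27 ± 0.09 at 80 cGy. Of the 8 measured, 4 were on the higher and 4 on the lower side, with a median of 0.05, so the list did not move as a whole. TGF-beta targets differed by 0.36 ± 0.16 with 16 of 17 genes on the higher side, and basal epithelium by -0.70 ± 0.38 with 19 of 20 on the lower side. Squamous epithelium differed by -1.06 ± 0.52 and the mesenchymal list by 0.35 ± 0.30. Fibroblasts with extracellular matrix differed by 0.36 ± 0.39, with 22 of 23 genes on the higher side, and skeletal muscle by 0.74 ± 0.91. Adjusted over the list alone, without correction for the number of lists, 4 genes passed in limma and 0 over all genes. These were the TGF-beta targets Smad7 (0.75 ± 0.23) and Pmepa1 (0.74 ± 0.24), both feedback inhibitors of TGF-beta signalling, and the Hedgehog genes Hhip (1.80 ± 0.56), an inhibitor that binds the ligand, and Gli3 (0.73 ± 0.23), a transcription factor that acts largely as a repressor. The permutation test called 0 of 37 lists (lowest adjusted p = 0.634), and Hedgehog alone had an unadjusted p under 0.05 (permutation p = 0.0171, exact enumeration 0.0169). With only the 10 sham tumours whose codes begin with 5 as controls, the Hedgehog difference was 0.36 and passed (permutation, adjusted p = 0.00333); with the 8 whose codes begin with 6 it was 0.16 and did not pass (permutation, adjusted p = 0.674), so its size depends on the controls. Camera with its preset correlation called 4 lists, TGF-beta targets higher and basal epithelium, squamous epithelium and hypoxia lower. With an estimated correlation camera called 0, each of them at an adjusted p = 0.946, and fry called 0.

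Across the 4 groups together, limma's F test called 0 genes (lowest adjusted p = 0.533) with 501 at an unadjusted p under 0.05, and 2 genes, Aspa and Itprip, passed with array weights. The smallest p belonged to Plekhf2, with means of 7.72 in sham, 7.70 at 10 cGy, 7.39 at 30 cGy and 7.30 at 80 cGy, followed by Lpcat4, Hs3st1, Tph1, Klf10 and Zc3h10. Along dose, limma called 0 genes (lowest adjusted p = 0.157) with 901 at an unadjusted p under 0.05, and 25 passed with array weights. The slopes of smallest p were those of Hs3st1 (0.19 ± 0.04 log2 per 10 cGy), Plekhf2 (-0.056 ± 0.013), Cyp2j9 (-0.12 ± 0.03), Tbx15 (0.22 ± 0.05), Adat1 (0.059 ± 0.015) and Ap3s1 (0.081 ± 0.021). Plekhf2 passed in limma without 80 cGy replicate 2 (adjusted p = 0.0319). Among the 3 doses alone, limma's F test called 0 genes (lowest adjusted p = 0.999) with 482 at an unadjusted p under 0.05, and 0 with array weights. Its leading genes were Tph1, Zc3h10, Med10 and Gcdh together with 2 mesenchymal transcription factor genes, Foxf2 (means 5.95, 5.08 and 6.75 at 10, 30 and 80 cGy) and Prrx2 (6.29, 6.88 and 7.76).

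The variation among tumours was compared between Si and sham hosts. The root mean squared distance of a tumour to its group mean was 0.69 log2 per gene in sham, 0.68 at 10 cGy, 0.62 at 30 cGy and 0.59 at 80 cGy. The ratio of Si to sham was 0.916, which did not pass (permutation p = 0.11). Without 10 cGy replicate 1 it was 0.888 and passed (permutation p = 0.0166). It did not pass with any other tumour left out. Without sham replicate 16, the tumour most like 10 cGy replicate 1, it was 0.933 (permutation p = 0.207), so the pass rests on that tumour.

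The log2 differences of 12123 genes at 10 and 30 cGy correlated at 0.42 across genes, those at 10 and 80 cGy at 0.12 and those at 30 and 80 cGy at 0.28. Genes are not independent replicates, and the 3 comparisons share their sham tumours. Simulated unchanged groups set against the same controls gave mean correlations of 0.35, 0.32 and 0.33, and 41.8%, 83% and 59.8% of simulated sets reached the observed value. The observed covariance less the simulated one was -0.00062, -0.017 and -0.0055. With the sham tumours split into separate control sets, the correlations were 0.004, -0.16 and -0.04. A shared effect of the doses beyond the shared controls was not detectable.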

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

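The search for single tumours far from their group was planned, the genes and lists it covered were chosen with the results in hand, and the test of the unnamed probe sets was chosen only after the named genes had been seen. A tumour is given here where its gap to the nearest other tumour of a dose group of 8 to 10 exceeded Dixon's limit as a share of the group's range. The search covered the 37 list scores, the 15 genes always given and the genes of smallest p for all Si hosts in each dose group, and the genes of smallest p for a dose in that dose's group. It did not cover other members of the lists or the sham group. Of 263 tests, 27 found such a tumour, while chance gives about 1 in 20, or 13.2.

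Several of these values fell in the same tumours. In 10 cGy replicate 1 the lowest values of the group were -3.20 for the luminal epithelium score, -2.71 for the epithelial junction score, 6.38 for Krt18, 7.01 for Krt8 and 5.56 for Cdh1. In 30 cGy replicate 4 they were -2.26 for luminal epithelium, -2.54 for epithelial junctions, 6.54 for Cdh1 and 6.66 for Kit. In 30 cGy replicate 1 the scores of skeletal muscle (6.28), adipocytes (4.17), endothelium (0.89) and oxidative phosphorylation (0.76) were the highest of the group, the cell cycle score (-1.23) the lowest, and Zfp458 (6.43) the lowest.

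The other values were in single tumours. In 10 cGy replicate 6 the hormone receptor score was 1.34, and in 10 cGy replicate 8 the mast cell score was 0.59 and Nrip2 was 4.60. Dennd4c was 9.11 in 10 cGy replicate 4, Nxf1 was 11.04 in 10 cGy replicate 3, Mki67 was 9.49 in 10 cGy replicate 5 and Cdkn2a was 9.11 in 10 cGy replicate 9. At 80 cGy, Lpcat4 was 11.22 in replicate 7, Zbtb48 was 6.78 in replicate 2, Mrpl54 was 8.51 and Zc3h10 was 6.85 in replicate 3, and Atg12 was 9.02 in replicate 5.

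Among 6342 probe sets without a single gene symbol that passed the same level filter, limma called 1 at 30 cGy. Probe set 10343881, unnamed here, had means of 7.03 ± 0.37 in sham (SD, n = 18), 6.94 ± 0.36 at 10 cGy (SD, n = 9), 6.23 ± 0.18 at 30 cGy (SD, n = 10) and 6.67 ± 0.39 at 80 cGy (SD, n = 8). Its difference at 30 cGy was -0.80 (limma adjusted p = 0.0026), and it was also the single call of limma's F test over the 4 groups (adjusted p = 0.0241). It was singled out after its values were seen.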

How the results depend on the processing

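Alternatives using the unnamed probe sets, the junction score, or the data without muscle-rich tumours or the most alike pair were chosen after seeing the data; the others were planned. Of 737 comparisons of a gene count, list count, spread ratio or dose similarity with its main value, 716 were the same. Of 3962 comparisons for single named values, 3948 were the same, 14 passed newly and 0 reversed. Here the same means that a value failed adjustment in both settings, whatever its sign. Since 0 passed in the main setting, a turned sign alone could not count as reversed, so these counts do not show stable signs. The sign of the top genes turned in 0 of 1670 comparisons, but these genes were chosen for their small p in the same data.

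Against limma's 0 genes for all Si hosts, the replicate number as a block gave 6, the array set as a block 1 (Snord53), and leaving out single tumours 0 to 1 (Lpcat4 without 10 cGy replicate 5, Snord49b without sham replicate 12). At 80 cGy array weights gave 30, the replicate block 1 (Krtap5-1), the 2 groups alone 1 (Hs3st1), the array set block 1 (Snord53) and left-out tumours 0 to 1 (Itprip without 80 cGy replicate 7). The F test over 4 groups gave 2 with array weights and 1 with the array set block (Snord53). The dose slope gave 25 with array weights, 1 with the array set block (Snord53) and 0 to 1 with left-out tumours (Plekhf2 without 80 cGy replicate 2, Itprip without replicate 7). For these shifts the cause was not tested. Camera with its preset correlation called 4 lists for all Si hosts, 11 at 10 cGy, 7 at 30 cGy and 4 at 80 cGy, and 0 with an estimated correlation; the permutation test called 1 list, Hedgehog, at 80 cGy with sham codes beginning with 5 alone. The spread ratio lay between 0.888 (without 10 cGy replicate 1) and 0.933 with left-out tumours.

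Tumours with the same replicate number did not deviate together (52 pairs, mean correlation -0.082, 10 above 0.1), so the number does not pair them; apart from the 6 and 1 genes above, the block changed no count. Array set A holds 1 tumour at 80 cGy, which was assumed to vary like the others in limma and left that list comparison not run. RMA values near the background level bound how small a change of a weakly expressed gene can be seen.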

Other observations

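The bound for microRNA genes was written before its value was seen; the other tests of this part were chosen only after the results they bear on had been seen. The epithelial junction score was unevenly spread, and the widest gap that left at least 6 tumours on either side lay between -1.36 and -0.70. Whether this gap separates clusters was not tested, and a continuous spread is not excluded. Below it were 9 tumours (5 sham, 1 at 10 cGy, 1 at 30 cGy and 2 at 80 cGy) and above it 36, and relations were computed on each side, not pooled. Genes shared with the junction list were left out of the other list. Of 72 relations between the junction score and another list on 1 side of the gap, 7 passed adjustment above the gap and 1 below it.

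Above the gap, luminal genes followed the junction score with r = 0.69 (permutation p = 1e-05, the smallest these permutations can give; rho = 0.61, p = 0.00013; adjusted p = 0.00036), and r was 0.61 without the 2 tumours farthest from the median. Mammary stem and progenitor genes had r = 0.68 (permutation p = 1e-05; rho = 0.60, p = 9e-05; adjusted p = 0.00036; 0.54 without the 2 farthest). Mesenchymal genes went the other way, with r = -0.64 (permutation p = 4e-05; rho = -0.58, p = 0.00039; adjusted p = 0.00096; -0.55 without the 2 farthest). Lists of stromal cells were also negative, with r = -0.51 for fibroblasts (permutation p = 0.00143; rho = -0.51, p = 0.00165; adjusted p = 0.0256; -0.47), -0.50 for endothelium (p = 0.00178; rho = -0.57, p = 0.00033; adjusted p = 0.0256; -0.48), -0.49 for mast cells (p = 0.00327; rho = -0.59, p = 0.00021; adjusted p = 0.0384; -0.51) and -0.46 for macrophages (p = 0.00427; rho = -0.56, p = 0.00061; adjusted p = 0.0384; -0.40). Within the 2 sets of arrays described further on, the 7 values of r kept their sign, from 0.42 to 0.76 for the positive lists and from -0.89 to -0.25 for the negative ones. Below the gap, squamous genes had r = 0.89 over 9 tumours (exact permutation p = 0.00413; rho = 0.75, p = 0.0255; adjusted p = 0.0384), which came to 0.40 without the 2 farthest tumours and so rests on them. The split mattered: at the next 2 widest gaps, which left 37 and 33 tumours above, 6 relations passed above each. Luminal, stem, mesenchymal and fibroblast genes passed at all 3 gaps. Mast cells and endothelium did not pass with 37 tumours above, where nerve and Schwann cells passed instead, and macrophages did not pass with 33. Below the gap the passing lists differed among the 3 splits, and squamous genes passed at 2 of them.

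Genes of small nucleolar RNAs, which guide chemical modification of ribosomal RNA, were mostly lower in Si hosts, a pattern noticed after the values were seen. Of 50 such genes 47 were lower, and their mean score differed by -0.23 ± 0.09 (permutation p = 0.00615), with 24 of 27 tumours below the sham mean. By dose the differences were -0.12 (10 cGy, permutation p = 0.293), -0.32 (30 cGy, permutation p = 0.00641) and -0.23 (80 cGy, permutation p = 0.0869), and Snord87 (-0.55 ± 0.13), Snord49b (-0.47 ± 0.11) and Snord82 (-0.60 ± 0.15) had the smallest p. Within array set A the difference was -0.27 (permutation p = 0.0429) and within set B -0.24 (permutation p = 0.0263). Against sham tumours of code 5 alone it was -0.18 (permutation p = 0.0498) and against those of code 6 alone -0.29 (permutation p = 0.0108).

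The tables argue against lower mRNA levels of the host genes as the whole cause. The 29 of 50 snoRNAs with a single named host kept differed from their 25 hosts by -0.22 ± 0.06 (the other 21 were not tested). The hosts stood at -0.007 ± 0.039. Array values give mRNA levels, so transcription of the hosts was not itself measured and remains open. The tables also argue against the array differences seen in the unnamed probe sets. With that component as a covariate the difference was -0.26 ± 0.08. Shuffles of the tumours put as many snoRNA genes on 1 side in 3.16% of 10000 draws. SnoRNAs less microRNAs differed by -0.29 ± 0.09, with the 62 microRNA genes at 0.06 ± 0.06. The bound written beforehand for this difference was met. These values argue against a lower recovery of short RNAs as a class, as far as the microRNA genes measured report it. The microRNA genes had a median level of 5.86, against 7.75 for the snoRNA genes. The level filter of 5.67 is the median of the table and not a floor, since values ran down to 1.34. The 15 microRNA genes at snoRNA levels differed by 0.06 ± 0.07. SnoRNAs less these 15 differed by -0.29 ± 0.11. How well the microRNA probe sets register a loss was not tested, so a lower recovery is not excluded. Lower snoRNA abundance in tumours of irradiated hosts may be pursued as a hypothesis, and RNA quality was not tested.

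The arrays were divided into 2 sets along a component of 1112 of the unnamed probe sets. These were chosen by mean level from 1998 control-like probe sets, which share 1 range of identifiers and are absent from the annotation. They do not stand for all unnamed probe sets. The component held 13.1% of the variance of the 1112 and correlated at 0.72 with the sixth component of the named genes. The cut was placed at the widest gap away from the ends, 1.47, on scores from -11.52 to 8.71. Whether these are separate sets was not tested, and a continuous spread is not excluded. Set A held 8 and set B 2 of the sham tumours with codes beginning with 5, against 1 and 7 of those with 6; at 10 cGy the split was 3 and 6, at 30 cGy 5 and 5, and at 80 cGy 1 and 7. With the set as a block limma called 1 gene for Si against sham, so the tables argue against array sets that hide many differences. Sham tumours of code 6 differed from those of code 5 in 0 genes by limma, with 1320 at an unadjusted p under 0.05. Whether processing or the hosts separate the sets is not given in the sources used here, and no biological explanation was tested.

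Tumours whose codes share a stem could come from a single host, but this cannot be told from the 8 pairs available. Their mean correlation after removing group means was 0.083, against -0.092 for random pairs, and 3.17% of 10000 draws were as high. Without sham replicates 5 and 6, the most alike of these pairs, 16.98% of draws reached the value of the other 7, -0.004.

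Other splits of the 45 tumours into groups of the same sizes do not exclude chance for the counts of genes at an unadjusted p under 0.05. Of 100 splits, the real one included, 28 gave as many as the 706 for all Si hosts, 56 as many as the 443 at 10 cGy, 45 as many as the 540 at 30 cGy and 23 as many as the 845 at 80 cGy, with 2047, 1798, 2090 and 2285 in the highest other split. For the F test over 4 groups 51 gave as many as 501 (highest other 1659), for the dose slope 21 as many as 901 (2453) and for the test among doses 54 as many as 482 (1658).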
